A study of Mus musculus with 8 samples.

How the data were processed

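Colon RNA of 8 male mice was measured on Agilent 2-colour mouse arrays, with 1 array per mouse. Per the labels, 4 arrays hold RNA of Mdr1a-/- mice with a high colonic histological injury score and 4 hold RNA of FVB/N mice with a low score, all on the AIN-76A control diet and aged 21 to 24 weeks. Mdr1a-/- mice lack the drug efflux transporter encoded by Abcb1a and are kept on the FVB/N background. Per the labels' protocols, each sample was labelled with Cy3 and hybridised against a common reference labelled with Cy5, which pooled RNA of small intestine, colon, kidney, liver and fetuses of Swiss mice. No dyes were swapped. Each slide held 1 array, so slide could not be tested as a batch.

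The deposited array files give, per the file headers, the mean foreground and local background intensity of each spot in both channels, with no flags and no pixel medians. They also hold a normalized log2 ratio. The authors named limma in the submitters' processing notes with no version, and the deposited description names loess. That log2 column was checked against the intensities: local background subtraction and loess over all spots of Cy5 over Cy3 gave the deposited log2 values to within 3e-13 on every array. Its direction is thus reference over sample, opposite to the deposited description, and the sign was turned before use. Its median per array lay between 0.0149 and 0.0319, and it was missing for 312 to 536 spots per array, as many as had a channel at or below its background. A series-wide table of the authors holds the same log2 values and was not used further. The authors' deposited table of fold changes gives a log2 fold change, a mean log2 intensity, a t score, a p-value and an adjusted p-value for 35449 of 44290 spots. The deposited description calls its fold changes log10, but their slope on the arrays' log2 fold changes was 0.87 without background subtraction and 0.589 to 0.621 with normexp. The table's mean intensities had a slope of 1.02 on the arrays' mean log2 intensities without background subtraction and 0.757 to 0.778 with normexp, so its fold changes are read as log2 here. The image analysis program is not given in the sources used here.

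The intensities were analysed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0. Spots of the same probe were averaged, which left 41174 probes, and values are log2(sample / reference). Groups were compared by lmFit and eBayes without covariates, two-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes. Log2 fold changes are Mdr1a-/- high minus FVB/N low, given with the standard error. A probe was above background on an array when its Cy3 net signal exceeded the 95th percentile of 314 negative control spots. A gene above background on no array of a group is given as "at least N-fold", from loess and Aquantile normalized Cy3 values, which are open to dye bias because no dyes were swapped.

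Accessions named 22072 probes through RefSeq annotation of the GRCm38.p6 assembly, and current or older symbols of the authors' table named 6280 and 4211 more. The remaining 8611 keep the name or probe identifier of the files. No genome build is named for the arrays, so no coordinates are given.

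Before the data were examined, 27 gene lists, the design and the rule for named genes were fixed. Gene lists were tested by camera with a preset inter-gene correlation of 0.01 on the brightest probe per gene, adjusted over the 27 lists. The rule names every probe of Abcb1a and Abcb1b, the 12 genes with the largest positive and the 12 with the largest negative fold change, and the 3 members of each list with the smallest p. The 24 had to be called, have a single symbol, separate the groups on all 8 arrays and be above background on the 4 arrays of the higher group. Replicate numbers of the 2 groups are shared in the labels, and a replicate block was among the alternatives, with scan day as a block, other background, normalization, filter, weight and threshold settings, and each array left out in turn. The arrays were scanned on 3 days, numbered here in order: day 2 held 2 arrays of each group, day 3 held 1 Mdr1a-/- and 2 arrays labelled FVB/N, and day 1 held 1 Mdr1a-/- array.

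The fit was tested on simulated data with the spread of these arrays. Of 100 probes changed by 1 on the log2 scale, 25% were recovered among 41174, and of 100 changed by 2, 81%, with 7 false calls. In that test, 2 of 2 shifted lists passed, also with an estimated correlation, and 1 of 25 unshifted lists passed with the preset one. The simulated genes were drawn independently, so this test does not cover lists whose genes are correlated.

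Foreground to background in the Cy3 channel, as medians, was between 2.55 and 3.40 on the 8 arrays, and 67% to 86.3% of probes were above background. The 4 arrays per group limit the precision, since each group rests on 4 mice.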

Results

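The series asked how the colon transcriptome of Mdr1a-/- mice with a high colonic histological injury score differs from that of FVB/N mice with a low score. Mdr1a-/- mice develop colon inflammation and serve as a model of inflammatory bowel disease. Colon RNA of 4 mice per group was hybridised, each on its own array against a common reference. Genotype and score change together between the groups, and the mice were chosen on their score, so the comparison cannot part one from the other. Between 27596 and 35541 of 41174 probes were above background per array. Correlations of log2 ratios across probes were 0.678 to 0.802 between arrays of 1 group and 0.565 to 0.73 between arrays of different groups.

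The disrupted gene was looked at first. The single probe of Abcb1a (A_51_P155445) had a log2(sample / reference) of -0.88 ± 0.12 (SD, n = 4) in Mdr1a-/- mice and -0.48 ± 0.35 (SD, n = 4) on the arrays labelled FVB/N. The log2 fold change was -0.40 ± 0.19 (SE, limma adjusted p = 0.362), with a 95% interval from -0.83 to 0.02, and the probe was above background on 3 and 4 arrays. With scan day as a block it was -0.33, and within scan days 2 and 3 it was -0.28 and -0.40. The authors' deposited table gives -1.62 for the same probe (adjusted p = 9.75e-05), outside that interval. The 3 probes of its paralog Abcb1b, another drug efflux transporter, had fold changes of 0.61 ± 0.18, 0.59 ± 0.15 and 0.40 ± 0.24 (SE, limma adjusted p = 0.115, 0.0771 and 0.507), against -0.69, -0.26 and 0.08 in the authors' deposited table. Whether the Abcb1a probe lies in the disrupted part is not given in the sources used here, and a probe outside it need not differ. The authors' deposited table does call this probe lower for the same comparison, so the probe can separate these groups. The labels are therefore in doubt. Of the files labelled FVB/N, 0 of 4 are on a slide that the protocol lists, against 3 of 4 Mdr1a-/- files. That Abcb1a did not separate the groups on the arrays does not tell which label is off. The second group, with 0 of 4 files on a listed slide, is called the arrays labelled FVB/N throughout. The name Mdr1a-/- mice is also taken from the labels, and that genotype was not verified here. Every direction below rests on these labels.

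**Figure D1:**
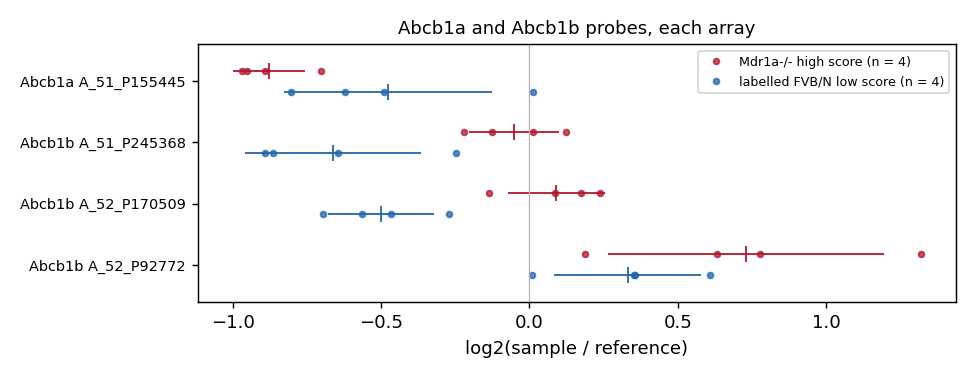
Log2(sample / reference) of the Abcb1a and Abcb1b probes on each of the 8 arrays. Points are arrays, ticks are group means and bars are SD (n = 4). The Abcb1a values overlap between the groups.

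Between the groups, 628 probes were higher in Mdr1a-/- mice and 598 were lower (limma, adjusted p under 0.05), which is 1.53% and 1.45% of the probes tested. They belong to 495 and 490 named genes. The groups did not overlap for 1224 of the 1226 called probes and for 4221 (10.3%) of all probes tested, where chance gives 2.86%. Inflammatory mediators were among the genes that rose most: the neutrophil alarmins S100a8 and S100a9 were 25.8-fold and 18.1-fold higher, the chemokines Cxcl11, Cxcl10 and Cxcl9 were 21.6-fold, 19.1-fold and 12.5-fold higher, and the matrix protease Mmp3 was 16.8-fold higher. Among the genes that fell most were the oxidase Hao2 (13.2-fold lower), the epithelial gasdermin Gsdmc2 (12.6-fold), the peptide transporter Slc15a1 (8.32-fold) and the chloride-bicarbonate exchanger Slc26a3 (5.8-fold).

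For S100a8 the log2 fold change was 4.69 ± 0.54 (SE, limma adjusted p = 0.0029). The rest of the 12 highest were Retnlg, the tryptophan-degrading enzyme Ido1 (3.99 ± 0.44), the lectin receptor Clec4d (3.95 ± 0.42), Plet1 (3.86 ± 0.35), the secreted phospholipase Pla2g2a (3.41 ± 0.36) and the protease inhibitor Serpina3g (3.23 ± 0.43). In Mdr1a-/- mice S100a9 and Plet1 were near saturation on 3 arrays, S100a8 and Ido1 on 2 and Pla2g2a on 1. On the arrays labelled FVB/N Cxcl11 was above background on 1 array, S100a8 and Mmp3 on 2, and Clec4d, Cxcl9 and Serpina3g on 3. Slc15a1 was above background on 3 of the 4 Mdr1a-/- arrays. The exact folds of these genes and their order are therefore not determined. Retnlg, a resistin-like neutrophil product, was above background on 0 of the 4 arrays labelled FVB/N and was at least 20.9-fold higher in Mdr1a-/- mice by the Cy3 channel alone. Its ratio to the reference gave 18.1-fold (limma adjusted p = 0.0291), so 20.9 is no lower limit on the ratio scale. Its call was lost in 7 of the 8 fits that left out 1 array, all but the one without Mdr1a-/- replicate 2, with adjusted p up to 0.0962. The 12 lowest also held the distal homeobox gene Hoxd13 (-2.96 ± 0.62), the elastase Cela1 (-2.79 ± 0.38), the cytochrome P450 Cyp2c40 (-2.77 ± 0.28), Nxpe5 (-2.65 ± 0.19), the slow troponin Tnni1 (-2.65 ± 0.28), the cation channel Trpv3 (-2.64 ± 0.35), AI854703 (-2.54 ± 0.29) and the sugar phosphate exchanger Slc37a2 (-2.52 ± 0.26). Hoxd13 stood at 2.54 in Mdr1a-/- replicate 3 and between -0.56 and -0.24 in the 3 other Mdr1a-/- mice. Its call was lost in 7 of the 8 fits that left out 1 array, all but the one without that replicate, with adjusted p up to 0.118. The other 22 of these 24 genes were called in all 8 such fits.

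**Figure D2:**
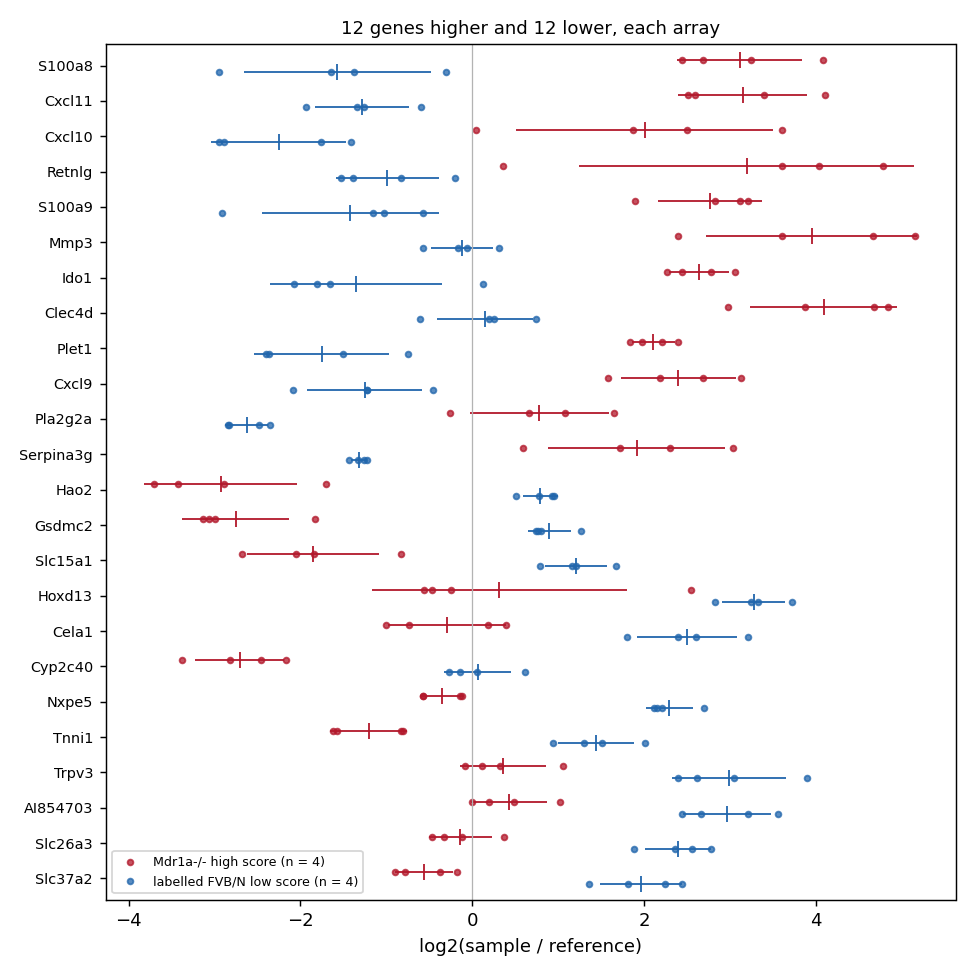
Log2(sample / reference) on each array for the 12 genes with the largest rise and the 12 with the largest fall. Points are arrays, ticks are group means and bars are SD (n = 4). The naming rule required the 4 arrays of one group to lie beyond the 4 of the other.

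Fewer probes passed with scan day in the fit. With scan day as a block 133 probes were higher and 115 lower, and 246 of these 248 were among the 1226. Day 1 holds only Mdr1a-/- replicate 4, so with the block that array adds nothing to the group contrast. Leaving that array out with no block left 250 higher and 247 lower, so the smaller counts cannot be put down to scan day alone. The median size of the log2 fold change over the 1226 was 1.10 with the block and 1.14 without, and the block leaves 4 residual degrees of freedom in place of 6. Deviations from the group means correlated at -0.04 on average between arrays of different groups scanned on the same day and at 0.02 between those of different days. Within scan day 2 (2 arrays against 2), in a fit added after seeing the data, no probe passed. With the block, 20 of the 24 passed, the exceptions being Cxcl10, Retnlg, Hoxd13 and Trpv3 (adjusted p = 0.0529, 0.0673, 0.158 and 0.0529). Their log2 fold changes with the block were 3.60 ± 0.59, 3.88 ± 0.70, -2.54 ± 0.63 and -2.52 ± 0.41, against 4.26 ± 0.68, 4.18 ± 0.82, -2.96 ± 0.62 and -2.64 ± 0.35 without it. Of all 66 called probes that the rule names, 45 passed with the block, and C1qc, H2-DMb1, Mki67, Ocln, Cldn3 and Pck1, named below, did not (adjusted p = 0.0554, 0.104, 0.0888, 0.118, 0.166 and 0.192). Their fold changes with the block were 1.20 ± 0.20, 1.19 ± 0.25, 1.40 ± 0.28, -1.01 ± 0.23, -0.81 ± 0.21 and -1.36 ± 0.37. Leaving out Mdr1a-/- replicate 1 or 4, or labelled FVB/N replicate 1, 2, 3 or 4, left 352, 250, 339, 403, 285 and 303 probes higher. The counts lower were 340 and 247 without Mdr1a-/- replicate 1 or 4, and 317, 289 and 309 without labelled FVB/N replicate 1, 3 or 4.

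Of the 27 gene lists, 21 passed camera with the preset correlation, 10 of them shifted upward and 11 downward. With an estimated correlation 0 passed, with adjusted p between 0.0977 and 0.813, and with fry 16 passed. Within scan day 2 19 lists passed. Day 3 holds a single Mdr1a-/- array, replicate 3, so shifts within it are given without a test and cannot part scan day from that mouse. The lists below that passed camera but missed it within day 2 were mitochondrial respiration and endothelium (adjusted p = 0.161 and 0.457). The shifts below are means of log2 fold changes over the measured members.

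The list of interferon response and antigen processing genes shifted upward. Of 36 measured members 20 were higher, 0 lower and 16 did not pass, and 32 were higher when adjusted over the list alone. Besides Cxcl11, the GTPases Iigp1 and Gbp3 rose by 3.19 ± 0.32 and 3.19 ± 0.34 (SE, limma adjusted p = 0.00194 and 0.00216), with Iigp1 near saturation on 1 Mdr1a-/- array. The list shifted by 1.79 (camera adjusted p = 4.53e-24), and adjusted p = 0.117 with an estimated correlation. The shift was 1.57 with scan day as a block, 1.94 within day 2 and 1.02 within day 3.

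The lists of neutrophil and acute inflammation genes and of macrophage and dendritic cell genes also shifted upward. Of 32 neutrophil and acute inflammation genes 8 were higher and 24 did not pass, and 24 were higher when adjusted over the list alone. S100a8 and S100a9 led, followed by the formyl peptide receptor Fpr2 (2.24 ± 0.37, adjusted p = 0.0131), whose call was lost without labelled FVB/N replicate 3 (adjusted p = 0.0501). The list shifted by 1.62 (camera adjusted p = 3.01e-14), and adjusted p = 0.128 with an estimated correlation. The shift was 1.37 with scan day as a block, and 1.39 and 1.33 within days 2 and 3. Of 25 macrophage and dendritic cell genes 10 were higher and 15 did not pass, and 21 were higher when adjusted over the list alone. The NADPH oxidase subunits Cybb and Ncf4 rose by 2.20 ± 0.17 and 1.89 ± 0.18, and the complement gene C1qc by 1.23 ± 0.16 (SE, limma adjusted p = 0.000994, 0.00167 and 0.00492). This list shifted by 1.08 (camera adjusted p = 7.99e-15), and adjusted p = 0.0977 with an estimated correlation. The shift was 0.99 with scan day as a block, 1.07 within day 2 and 0.87 within day 3.

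The lymphoid and MHC class II lists shifted upward by camera. Of 29 T and NK cell genes 5 were higher (9 adjusted over the list alone), among them the chemokine Ccl5 (1.75 ± 0.23) and the co-receptor Cd6 (1.33 ± 0.16), with limma adjusted p = 0.00525 and 0.00407. Of 14 genes of MHC class II presentation 1 was higher (4 adjusted over the list alone), H2-DMb1 (1.19 ± 0.21, adjusted p = 0.0193). Its call was lost in 5 of the 8 fits that left out 1 array, those without Mdr1a-/- replicate 1 or 4 or labelled FVB/N replicate 1, 3 or 4, with adjusted p up to 0.0708. Of 22 B and plasma cell genes 0 were called (2 adjusted over the list alone), and the transcriptional coactivator Pou2af1, with the smallest p, did not pass (limma adjusted p = 0.0602). The shifts were 0.57, 0.53 and 0.55 (camera adjusted p = 1.09e-06, 3.28e-05 and 0.000342), and adjusted p = 0.192, 0.17 and 0.241 with an estimated correlation. The block on scan day gave 0.50, 0.49 and 0.46. Within day 2 they were 0.81, 0.69 and 0.94, and within day 3 they were 0.03, 0.19 and -0.25. Mdr1a-/- replicate 3, the only Mdr1a-/- array of day 3, had a mean of -0.12 for T and NK cells and 0.37 for B and plasma cells, against 0.38 to 0.52 and 1.00 to 1.40 in the other Mdr1a-/- mice. The B and plasma cell list also missed fry (adjusted p = 0.07).

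The matrix remodelling and cell cycle lists shifted upward, and the endothelial and adhesion list did so less firmly. Of 41 matrix and remodelling genes 9 were higher (17 higher and 1 lower adjusted over the list alone), led by Col18a1 (1.64 ± 0.17) and the collagenase Mmp13 (2.01 ± 0.23), with limma adjusted p = 0.0022 and 0.00293. Of 34 cell cycle genes 8 were higher (18 adjusted over the list alone), led by Mki67 (1.43 ± 0.24, adjusted p = 0.0142), whose call was lost without Mdr1a-/- replicate 4 (adjusted p = 0.055). Of 19 endothelial and adhesion genes 2 were higher, also adjusted over the list alone, the leukocyte adhesion molecules Vcam1 (2.30 ± 0.23) and Icam1 (2.17 ± 0.26), with limma adjusted p = 0.00206 and 0.00382. The shifts were 0.74, 0.76 and 0.32 (camera adjusted p = 4.28e-08, 3.94e-12 and 0.0363), and adjusted p = 0.192, 0.192 and 0.241 with an estimated correlation. The block on scan day gave 0.71, 0.64 and 0.34. Within day 2 they were 0.48, 0.90 and 0.20, and within day 3 they were 1.06, 0.25 and 0.55. The endothelial and adhesion list, with a median of 0.08, missed the threshold in 10 of 24 alternatives. Without Mdr1a-/- replicate 3 or labelled FVB/N replicate 1 or 4 its camera adjusted p was 0.24, 0.0567 and 0.0609. With array weights it was 0.0523, with dim probes left out 0.0522, with the mean over all probes of a gene 0.114, and with the pancreas covariate described below 0.234.

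The absorptive colonocyte list shifted downward. Of 35 measured members 10 were lower and 25 did not pass, and 16 were lower and 2 higher when adjusted over the list alone. The butyrate transporter Slc16a1 (-1.44 ± 0.13), Slc26a3 (-2.54 ± 0.24) and the proton pump Atp12a (-2.12 ± 0.21) led, with limma adjusted p = 0.00167, 0.00167 and 0.00196. The list shifted by -0.79 (camera adjusted p = 1.68e-11), and adjusted p = 0.0977 with an estimated correlation. The shift was -0.82 with scan day as a block, -0.67 within day 2 and -1.05 within day 3. Tight junction and adhesion genes shifted by -0.35 (camera adjusted p = 0.000104), and adjusted p = 0.171 with an estimated correlation. Of these 24 genes 2 were lower (6 adjusted over the list alone), Ocln (-1.10 ± 0.21) and Cldn3 (-0.79 ± 0.16), and each was lost in 7 of the 8 fits that left out 1 array, with adjusted p up to 0.0895 and 0.0969. Ocln kept its call only without Mdr1a-/- replicate 3 and Cldn3 only without labelled FVB/N replicate 1. The shift of the list was -0.34 with scan day as a block, -0.49 within day 2 and -0.11 within day 3.

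Lists of detoxification and oxidative metabolism shifted downward, with most of their members not passing. Of 73 genes of xenobiotic metabolism and transport 19 were lower, 0 higher and 54 did not pass, and 28 were lower and 1 higher when adjusted over the list alone. The cytochrome P450 Cyp2d34 (-1.89 ± 0.15), the monoamine oxidase Maob (-2.25 ± 0.18) and the sulfotransferase Sult1c2 (-2.47 ± 0.24) led, with limma adjusted p = 0.000994, 0.000994 and 0.0019. The list shifted by -0.53 (camera adjusted p = 5.17e-12), and adjusted p = 0.0977 with an estimated correlation. The shift was -0.49 with scan day as a block, -0.47 within day 2 and -0.52 within day 3. Of 50 genes of fatty acid oxidation and PPAR alpha targets 8 were lower (12 adjusted over the list alone), led by the thiolase Acaa2 (-1.28 ± 0.14) and the nuclear receptor Ppara itself (-1.27 ± 0.15), with limma adjusted p = 0.00274 and 0.00342. The mean of this list on the arrays labelled FVB/N was -1.21, -1.01, -1.10 and -1.30 in replicates 1 to 4, in the same order as that of the adipose list (-0.15, 0.75, 0.39 and -1.26), which also shifted downward. In Mdr1a-/- mice the means were -1.43, -1.35, -1.38 and -1.51 for this list and -1.06, -0.66, -1.12 and -1.16 for adipose tissue. Of 14 butyrate and ketone genes 3 were lower (4 lower and 1 higher adjusted over the list alone), among them Acss2 (-1.74 ± 0.18, adjusted p = 0.00216). The other called genes were Slc16a1, also an absorptive colonocyte gene, and Hadh, also a fatty acid oxidation gene, so these lists share members. The Hadh call was lost in 7 of the 8 fits that left out 1 array. It was also lost with scan day as a block (limma adjusted p = 0.112) and with the pancreas covariate described below (0.161). Of 53 genes of mitochondrial respiration and the TCA cycle 0 were called, also adjusted over the list alone, and Suclg2, with the smallest p, stood at -0.74 ± 0.18 (adjusted p = 0.064). These 3 lists shifted by -0.26, -0.33 and -0.16 (camera adjusted p = 6.25e-06, 0.00141 and 0.000853), and adjusted p = 0.117, 0.0977 and 0.117 with an estimated correlation. Their shifts were -0.23, -0.36 and -0.16 with scan day as a block. Within day 2 the shifts were -0.24, -0.41 and -0.09, and within day 3 they were -0.22, -0.29 and -0.26. The mitochondrial list also missed the threshold with global median centring (shift -0.06, adjusted p = 0.184).

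Secretory and defence genes of the epithelium went both ways. Of 21 goblet cell genes 1 was higher, the membrane mucin Muc4 (3.11 ± 0.25), and 3 were lower, among them Fcgbp (-2.19 ± 0.28) and the kallikrein Klk1 (-1.86 ± 0.28), with limma adjusted p = 0.000994, 0.00524 and 0.00875 and the same counts adjusted over the list alone. The list shift of -0.19 did not pass (camera adjusted p = 0.051). It passed in 8 of 24 alternatives, with shifts over all 24 between -0.33 and 0.16, among them -0.06 with scan day as a block, -0.21 within day 2 and 0.16 within day 3, the first 2 not passing. Leaving out Mdr1a-/- replicate 2 or 3 or labelled FVB/N replicate 1 gave adjusted p of 0.0101, 0.00799 and 0.0208. Of 29 epithelial defence and repair genes 7 were higher and 3 lower (13 and 6 adjusted over the list alone). Pla2g2a and the cornified envelope gene Sprr2h (2.72 ± 0.33, above background on 3 of the 4 arrays labelled FVB/N) rose, while the amino acid transporter Slc6a14 fell by 1.99 ± 0.18 (limma adjusted p = 0.00403 and 0.00165). That list shifted by 0.53 (camera adjusted p = 0.00304), and adjusted p = 0.241 with an estimated correlation. Its shift was 0.46 with scan day as a block, 0.51 within day 2 and 0.37 within day 3. Of 18 enteroendocrine genes 4 were lower and 1 higher (7 and 3 adjusted over the list alone), and the granins Chga and Chgb fell by 1.75 ± 0.23 and 1.24 ± 0.17, and the hormone Insl5 by 1.39 ± 0.21 (limma adjusted p = 0.00577, 0.00603 and 0.0106). With scan day as a block these 3 did not pass (-1.67 ± 0.28, -1.16 ± 0.19 and -1.26 ± 0.24, adjusted p = 0.0565, 0.0554 and 0.077). The list shifted by -0.38 (camera adjusted p = 0.00339), and adjusted p = 0.17 with an estimated correlation, and the shift was -0.32 with the block, -0.33 within day 2 and -0.30 within day 3.

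Lists of markers of tissue around the mucosa passed camera downward, and all 4 missed fry. The fry adjusted p was 0.0915 for pancreas, 0.0915 for adipose tissue, 0.163 for smooth muscle and 0.0534 for neurons and glia. The 17 measured pancreatic acinar genes shifted by -1.53 (camera adjusted p = 5.08e-07), and adjusted p = 0.241 with an estimated correlation, and the shift was -1.52 with scan day as a block, -0.94 within day 2 and -2.38 within day 3. Only Cela1 was called among them, also adjusted over the list alone. Their mean per array was 1.09, -1.39, -1.28 and -0.75 in Mdr1a-/- replicates 1 to 4 and 0.32, 2.03, 1.26 and 0.16 on the arrays labelled FVB/N. With this mean as a covariate, chosen after seeing the data, 141 probes were higher and 130 lower, and 44 of the 66 called probes that the rule names passed. The median size of the log2 fold change over the 1226 was 1.16, and the covariate leaves 5 residual degrees of freedom. Named genes that did not pass with it were Cxcl10, Retnlg, Hoxd13, Trpv3, Fpr2 and Cd6 (adjusted p = 0.0503, 0.0917, 0.106, 0.0553, 0.115 and 0.0512). Their fold changes with it were 4.99 ± 0.87, 4.92 ± 1.1, -3.53 ± 0.81, -2.69 ± 0.49, 2.13 ± 0.51 and 1.31 ± 0.23. The same holds for H2-DMb1, Mki67, Klk1, Chga, Insl5, Ocln and Cldn3 (0.0957, 0.0731, 0.0838, 0.0687, 0.0957, 0.154 and 0.283), at 1.30 ± 0.29, 1.60 ± 0.32, -1.83 ± 0.39, -1.62 ± 0.32, -1.35 ± 0.30, -1.11 ± 0.29 and -0.64 ± 0.22. It also holds for Pck1, S100b and Snap25 (0.22, 0.126 and 0.152), at -1.49 ± 0.45, -0.85 ± 0.21 and -1.16 ± 0.30. Cela1 did not pass either (-2.18 ± 0.41, 0.0655), but it is itself part of the mean. The adipose, smooth muscle and neuron shifts with the covariate were -0.50, -0.72 and -0.26. The 14 adipose genes shifted by -0.93 (camera adjusted p = 3.84e-05), and adjusted p = 0.241 with an estimated correlation, and Pck1 was called, also adjusted over the list alone (-1.53 ± 0.33, adjusted p = 0.0401). The Pck1 call was lost in 7 of the 8 fits that left out 1 array, all but the one without Mdr1a-/- replicate 3, with adjusted p up to 0.126. Smooth muscle (0 of 21 called, also adjusted over the list alone) and enteric neuron and glia genes (2 of 26 lower, also adjusted over the list alone) shifted by -0.39 and -0.22 (camera adjusted p = 0.000425 and 0.00671), and adjusted p = 0.315 and 0.241 with an estimated correlation. The adipose, smooth muscle and neuron shifts were -0.93, -0.33 and -0.24 with scan day as a block. Within day 2 they were -0.98, -0.75 and -0.40, and within day 3 they were -0.86, 0.29 and -0.01. The smooth muscle mean was 0.02 in Mdr1a-/- replicate 3 and between -0.89 and -0.61 in the other Mdr1a-/- mice. The 2 called neuron and glia genes were S100b (-0.81 ± 0.15) and Snap25, both lower, with limma adjusted p = 0.0213 and 0.0493, and 0.125 and 0.0683 with the block. Leaving out 1 array ended the S100b call without Mdr1a-/- replicate 1 or 4 or labelled FVB/N replicate 2, 3 or 4 (adjusted p up to 0.0754). It ended the Snap25 call in all fits but the one without Mdr1a-/- replicate 3 (adjusted p up to 0.139).

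**Figure D3:**
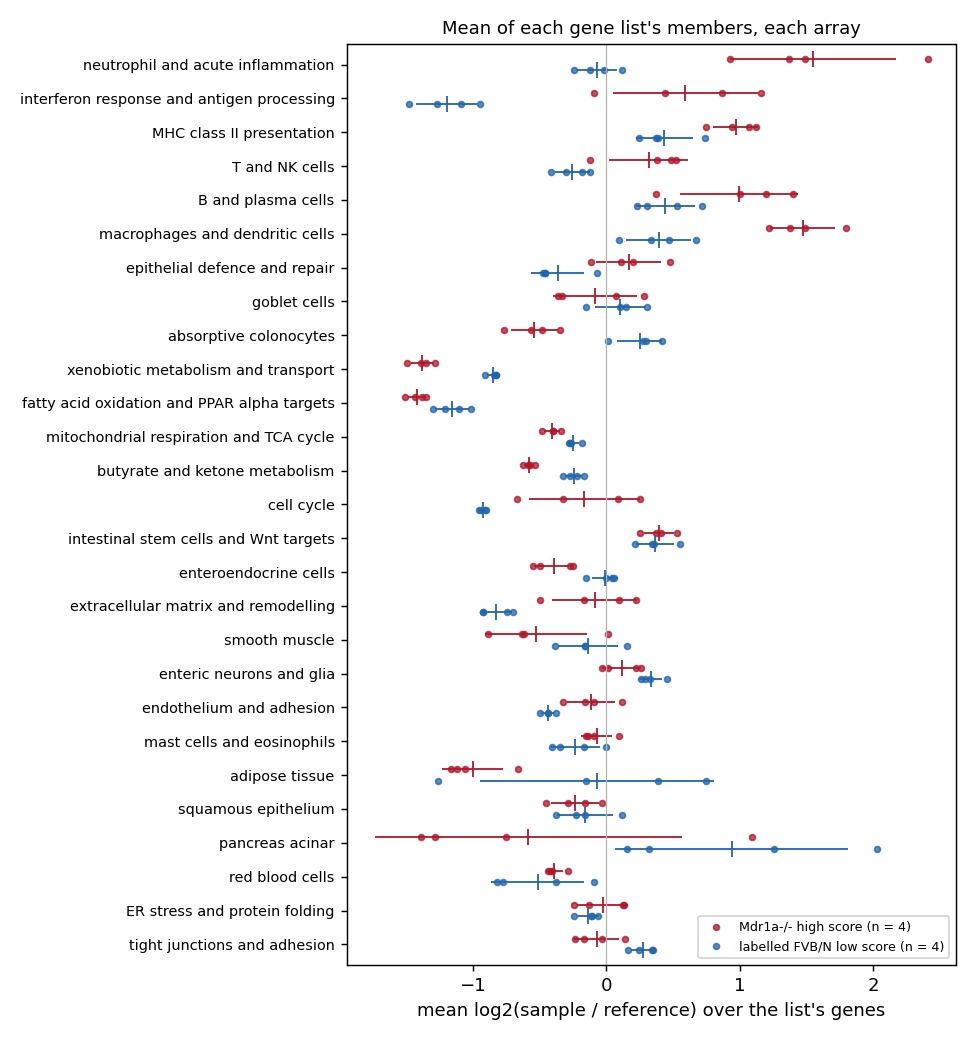
Mean log2(sample / reference) over the members of each of the 27 gene lists on each array. Points are arrays, ticks are group means and bars are SD (n = 4). The interferon means lie between -0.09 and 1.16 in Mdr1a-/- mice and between -1.48 and -0.95 on the arrays labelled FVB/N.

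The authors' deposited table calls 2236 spots higher and 1555 lower at its adjusted p under 0.05. Among 35055 probes with 1 spot in both sources, the authors' deposited table calls 3726, the arrays 1193, and both 1072, all of these in the same direction, where independent lists would share 127. These values are from the same study and the 2 sources are not independent.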

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

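No test in this part was chosen after the result was seen. In groups of 4 arrays, 116 sets of values were tested for a single array far from the other 3, and 7 stood apart, where chance gives about 5.8. All values are log2(sample / reference), or the mean of it over a list. Hoxd13 stood at 2.54 in Mdr1a-/- replicate 3, against -0.56 to -0.24 in the other Mdr1a-/- mice. Gsdmc2 stood at -1.83 in Mdr1a-/- replicate 2, against -3.13 to -2.99, and at 1.27 in labelled FVB/N replicate 1, against 0.74 to 0.80. Nxpe5 stood at 2.70 in labelled FVB/N replicate 3, against 2.12 to 2.21. In labelled FVB/N replicate 2 the epithelial defence and repair list stood at -0.0661, against -0.48 to -0.46, and the mitochondrial list at -0.18, against -0.28 to -0.26. The xenobiotic list stood at -0.91 in labelled FVB/N replicate 3, against -0.84 to -0.83.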

How the results depend on the processing

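All alternatives were planned except the pancreas covariate and the fits within a scan day, which were chosen after seeing the data. With a replicate block 310 probes were higher and 286 lower. Deviations of same-numbered arrays correlated at 0.06, 0.11, 0.03 and -0.03, within the range of other pairings (-0.154 to 0.148). No pairing by number was seen, which does not show that there was none. With scan day as a block 133 were higher and 115 lower, with array weights 1081 and 939, at adjusted p under 0.01 180 and 186, and with the pancreas covariate 141 and 130. Within scan day 2, with 4 arrays, 0 were higher and 0 lower (limma), and no counts are given for day 3. Leaving out 1 array gave 250 to 783 higher and 247 to 675 lower. Passing lists numbered 12 within day 3 and 0 with an estimated correlation, against 21. Within day 3, B and plasma cells turned to -0.25 and smooth muscle to 0.29. Day 3 holds a single Mdr1a-/- array, replicate 3, assumed to vary like the others, and its means of 0.37 and 0.02 lay apart from the other Mdr1a-/- mice (1.00 to 1.40 and -0.89 to -0.61). Scan day and that mouse cannot be parted there, and the cause was not tested. Other alternatives left the counts within 1.5 times, and Abcb1a stayed between -0.51 and -0.21 without passing. No other passing list or called named gene changed sign under any alternative. With a replicate block the endothelial list missed the threshold (adjusted p = 0.0584). Not run were pixel medians and spot flags, which the files used here do not hold. Signal over background limits dim probes.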

Other observations

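The tests on Abcb1a, on pancreatic genes and on cell types other than epithelium were chosen only after the result was seen, in whole or in part. The test of passing lists over the splits was also written down after results were seen. The epithelial share test was fixed before, but its wording as part of the cause came after.

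Lists not described above did not pass camera. The stem cell and Wnt list of 16 genes held 1 higher gene, the adhesion receptor Cd44 (1.58 ± 0.15 on the log2 scale, SE, limma adjusted p = 0.00167), and 2 higher and 1 lower when adjusted over the list alone. Its mean was 0.03 and its median -0.09 (camera adjusted p = 0.66, direction down). Of 17 mast cell and eosinophil genes 0 were called, with a mean of 0.16, a median of -0.01 and camera adjusted p = 0.759 (direction down). Of 25 ER stress and folding genes 1 was higher, the glutathione-degrading enzyme Chac1 (0.85 ± 0.16, limma adjusted p = 0.0228), and its call was lost in 5 of the 8 fits that left out 1 array, those without Mdr1a-/- replicate 2 or 4 or labelled FVB/N replicate 2, 3 or 4, with adjusted p up to 0.0824. With scan day as a block its adjusted p was 0.123, and with the pancreas covariate 0.178. The camera adjusted p of that list was 0.492. The squamous epithelium and red blood cell lists had 0 called genes and camera adjusted p of 0.368 and 0.645. Counts adjusted over the list alone were 3 higher for ER stress and 0 for the mast cell, squamous and red blood cell lists.

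The 8 arrays were also split in other ways. Of 35 splits 1, the real one, gave as many called probes as 1226, and the highest of the others gave 0. At unadjusted p under 0.05 the others gave up to 3761, against 6136. With 35 splits this cannot exclude chance. The other splits also mix the groups, so a true difference widens their spread and lowers their counts. For the passing lists, 1 of 35 splits reached the real 21 and the highest other gave 18. Splits with 2 arrays of each group on each side passed up to 11 lists (median 5.5), so camera with the preset correlation passes lists between arbitrary sets of these arrays. With scan day as a block 100% of the 1226 probes kept their direction, but this counts probes picked for their difference and so decides nothing about scan day.

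Abcb1a did not separate the groups on the arrays, while the authors' deposited table calls it lower by far. Background and normalization settings are argued against, since their lowest log2 fold change was -0.433, with a normexp offset of 10. Over all alternatives the lowest was -0.513, without labelled FVB/N replicate 1. Signal below background is argued against too, since 4 of the 4 arrays labelled FVB/N had the probe above the negative control limit. That the table was computed from these 8 arrays with another background correction is argued against: its fold changes were explained with R squared of at most 0.727 by the 8 arrays, against 0.91 to 0.926 for 5 settings of the fit here, none of which reached the 0.95 that the test had asked for. A candidate explanation is that arrays labelled FVB/N hold RNA of other mice than the FVB/N group of the table; 3 of the 4 Mdr1a-/- files and 0 of the 4 files labelled FVB/N are on a slide that the protocol lists. The 6 probes of Abcb1a and its neighbours that the authors' deposited table calls at 1.5-fold or more kept a median share of 0.134 of its fold change, against 1.08 for 1930 other probes, but the 95% bootstrap interval from -0.49 to 1.36 leaves this open and it cannot be told apart from other differences between the sources.

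The xenobiotic and fatty acid oxidation lists shifted downward together. Whether a lower share of epithelial cells was the whole cause is not decided by the test run. The macrophage list's median fold change exceeded that of neurons and glia by 1.25 (95% bootstrap interval 0.98 to 1.64), so these 2 list medians lay apart. The neuron and glia list itself missed fry (adjusted p = 0.0534). The difference between the medians could arise with or without a lower epithelial share as the cause. As part of the cause a lower share may hold. Of the 20 general epithelial markers 2 were called lower and 0 higher, with a median of -0.30 (interval -0.47 to -0.05). It differed from the xenobiotic list's median of -0.39 by 0.0914 (interval -0.23 to 0.40). That interval is wide and includes 0, so it neither shows nor excludes such a part. A difference in metabolic gene activity per epithelial cell stays open and was not tested, and neither was a difference in adipose tissue, whose list moved with the fatty acid list on the arrays labelled FVB/N.

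Pancreatic enzyme genes varied 10.7-fold in their mean between the lowest and the highest array. Pancreatic tissue in some dissected samples may be the source: the 17 acinar genes, 0 of which are in another list, had a median pairwise correlation of 0.876 over the 8 arrays, and the means differed by 3.43 on the log2 scale. How many of them colon itself expresses was not tested. A difference between the groups gave an exact two-sided permutation p of 0.0857, which does not exclude one; the bound first written for this test, p of at least 0.05, would have excluded it and was wrong on that point, since 4 against 4 mice can miss a difference of this size.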
